A study of Mus musculus with 74 samples.

How the data were processed

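Duodenum, jejunum and ileum of female mice were profiled by mRNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was captured with oligo(dT) beads, libraries were made with a BGI kit, and paired reads were sequenced on a DNBSEQ T7 instrument. Groups and replicate numbers were taken from the sample titles, which give segment, diet, genotype and a number. The genotype is an intestine-specific heterozygous knockout of Ripk1 against wild-type littermates, and the labels do not name the Cre line or the exons removed. The 74 libraries come from 25 mice if, as the titles imply, the same number in different segments is the same mouse. Within a group each number is then a separate animal.

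The deposited values are raw counts per gene symbol, with 1 column for each library. Per the submitters' processing notes, FastQC, Bowtie2, HISAT2 and SAMtools and the mouse builds GRCm39 and mm39 were used, with no versions. The counting tool, the annotation release and whether counting used strand are not given in the sources used here. Reads of near-identical genes could have been split or dropped in counting. Values of H2-Q10 and of members of the Cyp2c, Cyp3a, Gstm, Reg3, Mcpt, Saa, Ugt1a, Defa and Rpl3 pseudogene families are therefore uncertain, as are those of predicted Gm genes. The table holds 55367 genes with values. Another 31 lines at its end, 30 of them with a gene name, hold no values and were left out. The reference genome at hand is an older build than the one used for the counts, so no coordinates are given.

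Each library held 15220866 to 17127885 counts (median 16237687), and mitochondrially encoded genes took 4.41% to 10.8% of them. The single most abundant gene of a library took at most 5.60%. At these totals 3 counts over the 6 ND WT duodenum libraries correspond to 0.0307 CPM. Such floors cover counting error only. Replicate pairs were compared by a chi-square test of their counts, and the smallest of 193 values was 10.5 per degree of freedom, so no pair of replicates agreed within sampling noise.

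Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr and library sizes were scaled by TMM. Each segment was fitted with its 4 groups, and comparisons between segments with all 12 groups. Quasi-likelihood tests (glmQLFit with robust = TRUE and legacy = FALSE, glmQLFTest) were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were said to pass, rise or fall. The tests covered 16806 genes in the duodenum, 16710 in the jejunum, 17073 in the ileum and 18355 over all segments. Adjusted p-values of single genes are from edgeR throughout, and the standard error of a log2 fold change is its size divided by the square root of F. All tests are 2-sided. The 19 comparisons, the tests, 41 gene lists and the rule for named genes were fixed before the data were examined. Under the rule, among passing genes with a mean of at least 1 CPM, the 8 with the largest positive and the 8 with the largest negative log2 fold change were named. The rule adds up to 4 members with the smallest p of each list with a camera adjusted p under 0.05, and up to 2 of each other list. Immunoglobulin and T cell receptor segments and predicted genes were left out, and fewer genes are named here, in rank order. Some genes that the rule picked are not reported here. Where under 5 genes passed, the 5 with the smallest p qualified, and the predicted genes Gm3054 and Gm5420 were named after their values were seen. Gkn1, Gata4, Hoxc8 and other markers of position were also chosen after their values were seen.

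Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over the lists of a comparison, and again with an estimated correlation. Ripk1 was also compared by exact permutation of log2(CPM + 1), adjusted over its 6 comparisons. CPM of Ripk1 and of genes named by the rule use the scaling of the segment. CPM of Hoxb9, Hoxc6, Hoxc8, Hoxc9, Gata4, Fabp1, Fabp6, Gkn1, Cyp1a1, Ahrr and H2-Q10, and all figures, use a scaling over all 74 libraries. Opposition of diet and genotype effects was computed from mean log2 CPM, with 500 simulations of no effect of diet or genotype and with disjoint HFD WT libraries.

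Each test was checked on counts simulated independently for each gene, with 200 genes changed. In the HFD ileum 41.8% of 1.5-fold, 62.7% of 2-fold and 95.5% of 4-fold changes were recovered between HET and WT. In the HFD duodenum 13 unchanged genes were called, 8.90% of the calls.

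Alternatives planned in advance were other scalings, no filter, an earlier edgeR pipeline, limma-voom, DESeq2 1.42.0, only the 2 groups compared, a minimum log2 fold change of 1, the replicate number as a block, covariates for smooth muscle and B cell markers, removal of immunoglobulin, acinar, mitochondrial and hemoglobin genes, and leaving out each library in turn. Leaving out each library was planned only for comparisons of genotype or diet within a segment. For interactions and comparisons between segments it was not planned in advance. After seeing the data, 2 more alternatives were added. The first was a covariate for position, the mean log2 CPM of 11 Hox genes higher in ileum than in duodenum. The second left out 13 libraries of doubtful position, namely ileum libraries with under 1 CPM of Hoxb9, duodenum libraries with over 100 CPM of Gkn1 and jejunum libraries with over 2 CPM of Hoxc8. Same-numbered libraries of different segments deviated together in part (73 pairs, mean r 0.203, 55 over 0.1). The labels only imply that such libraries share a mouse, so the mouse was a block only as an alternative in comparisons between segments. The main fits of those comparisons therefore treat same-numbered libraries as independent, though they were not fully so.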

Results

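Polyadenylated RNA was measured in the duodenum, jejunum and ileum of female mice that carry one inactivated copy of Ripk1 in the intestine (HET) and of wild-type littermates (WT), kept on normal chow (ND) or on a high-fat diet (HFD). RIPK1 is a kinase and scaffold protein of signalling downstream of the TNF receptor. The 74 libraries form 12 groups. Each group holds 6 libraries, except for 7 in each HFD WT group and 5 in the HFD HET jejunum. Each library held between 15220866 and 17127885 counts (median 16237687), and between 22184 and 25000 genes had at least 1 count.

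Ripk1, the targeted gene, was lower in HET than in WT ileum on HFD. Its level there was 38.9 ± 8.74 CPM (SD, n = 6; range 28.4 to 52.2) in HET and 58.6 ± 10.1 CPM (n = 7; range 45.6 to 71.7) in WT, which is 66.4% of WT (log2 fold change -0.59 ± 0.16 SE, adjusted p = 0.00885; exact permutation p = 0.00641, 0.0385 over the 6 comparisons). On ND the ileal level was 39.7 ± 11.3 CPM in HET against 55.0 ± 7.05 CPM in WT (n = 6 each), or 72.2%, with an exact permutation p of 0.0217 (0.0476 adjusted) and a log2 fold change of -0.47 ± 0.16 that missed the threshold over all genes (adjusted p = 0.622). The duodenum held 33.2 ± 6.49 CPM in HET against 39.1 ± 6.58 CPM in WT on HFD (85.1%; exact permutation p = 0.145, 0.218 adjusted) and 36.2 ± 3.26 against 41.1 ± 2.72 CPM on ND (88.0%; exact permutation p = 0.0238, 0.0476 adjusted). In the jejunum HET stood at 96.7% of WT on HFD (exact permutation p = 0.756, also 0.756 adjusted) and at 88.0% on ND (exact permutation p = 0.210, 0.252 adjusted). No Ripk1 difference outside the HFD ileum passed over all genes, with adjusted p from 0.532 to 1.00. Which part of the gene was inactivated is not given in the sources used here, so these whole-gene counts can include reads from the altered copy. If only epithelial cells were targeted, muscle and lymphoid cells in the pieces would also keep both copies. Neither contribution was measured. The call in the HFD ileum was lost with covariates for muscle and lymphoid tissue (-0.32, adjusted p = 0.368), with a covariate for position along the intestine (-0.32, adjusted p = 0.738) and without 4 HFD WT ileum libraries of doubtful position (-0.52, adjusted p = 0.245). Over all alternatives the adjusted p ranged from 0.00307 to 0.738.

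**Figure D1:**
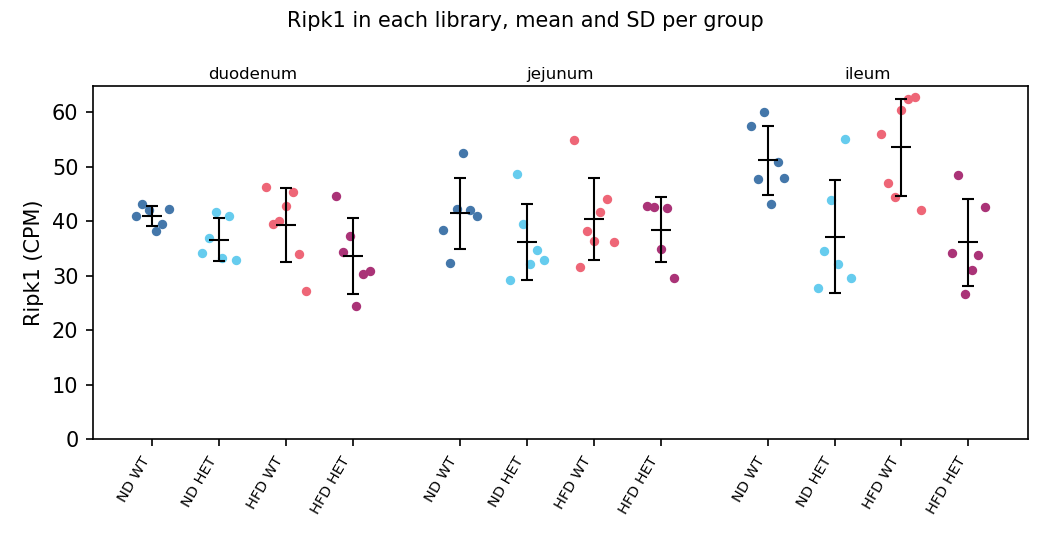
Ripk1 level of each library in CPM, scaled over all 74 libraries, with 1 point per library and bars for the mean and SD of each of the 12 groups. In the ileum on HFD the 6 HET libraries sit between 26.7 and 48.5 CPM and the 7 WT libraries between 42.1 and 62.8 CPM.

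As a check of the segment labels, the ileum of WT mice on ND was compared with the duodenum (n = 6 each). Fabp6, which binds bile acids in ileal cells, was higher in the ileum by 14.59 ± 1.10 (SE) on the log2 scale. Slc10a2, which takes up bile acids, rose by 9.84 ± 0.77, Nr1h4, the bile acid receptor, by 2.53 ± 0.22, and Slc51a, which exports bile acids, by 2.54 ± 0.25. Among proximal genes, Onecut2 (log2 fold change -9.53 ± 0.63) and Pdx1 (-10.01 ± 0.89), both transcription factors of the upper gut, Cck (-3.76 ± 0.32), a satiety hormone, and Fabp1 (-7.38 ± 0.65), a fatty acid binding protein, fell. Of the 15 measured distal identity genes 14 rose, and 14 did so adjusted over the list alone (camera adjusted p = 8.24e-21; adjusted p = 0.00148 with an estimated correlation). Of the 15 proximal identity genes 13 fell and 1 rose, with 13 and 1 adjusted over the list alone (adjusted p = 1.40e-12; adjusted p = 0.00318 with an estimated correlation). Cholesterol synthesis genes rose in 21 of 25 cases and fell in 1, or 22 and 1 adjusted over the list alone (adjusted p = 6.32e-18; adjusted p = 0.0299 with an estimated correlation), among them Tm7sf2 (1.68 ± 0.16) and Sqle (2.23 ± 0.24). Of 25 xenobiotic metabolism genes 19 fell, or 21 adjusted over the list alone (adjusted p = 2.33e-13; adjusted p = 0.0627 with an estimated correlation), among them Gsta1 (-5.19 ± 0.37) and Gstm6 (-4.73 ± 0.38). Oxidative phosphorylation genes fell in 28 of 29 cases, also adjusted over the list alone (adjusted p = 2.33e-13; adjusted p = 0.197 with an estimated correlation). In all, 7012 genes passed, 2738 higher and 4274 lower, and 6001 passed without the libraries of doubtful position.

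Between jejunum and duodenum of the same WT mice on ND, Slc5a8, a short-chain fatty acid transporter, was higher in the jejunum by 6.44 ± 1.22 on the log2 scale and Osr2, a transcription factor, by 4.09 ± 0.75. Slc5a8 was at 2.19 (adjusted p = 0.363) without jejunum ND WT library 4, and Osr2 at 6.63 without duodenum ND WT library 5. Pdx1 (-4.35 ± 0.59) and Slc40a1 (-5.20 ± 0.81), the iron exporter, were lower. Of 9 measured gastric markers 6 were lower in the jejunum, or 7 adjusted over the list alone (adjusted p = 9.05e-08; adjusted p = 0.160 with an estimated correlation). Gkn1, a stomach surface mucous cell gene, stood at 2937, 336 and 717 CPM in ND WT duodenum libraries 2, 4 and 6 and at 193 CPM in ND HET library 6, against at most 8.08 CPM in the other 21 duodenum libraries. Tff2, a gastric gland peptide, ranged from 0.484 to 57980 CPM over the 6 ND WT duodena. Pgc, the pepsinogen C gene, averaged 498.9 ± 646 CPM (SD) in the duodenum and 0.944 ± 0.537 CPM in the jejunum. In all 2546 genes passed, 840 higher and 1706 lower, but 932 passed without duodenum ND WT library 2, 1657 without library 6, and 11 without all libraries of doubtful position, where 3 of 22 genes under the naming rule kept their call.

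Of 25 xenobiotic metabolism genes 6 were lower on HFD than on ND in the duodenum of WT mice (n = 7 HFD, 6 ND), or 11 adjusted over the list alone (camera adjusted p = 6.65e-06; adjusted p = 0.843 with an estimated correlation). Cyp1a1, the cytochrome induced through the aryl hydrocarbon receptor, stood at 0.596 ± 0.538 CPM (SD) on HFD and 111 ± 36.2 CPM on ND (log2 fold change -7.52 ± 0.58 SE, adjusted p = 6.72e-08). Cyp2c29 (-5.37 ± 0.75), Gstm1 (-1.74 ± 0.25), Cyp2c66 (-1.97 ± 0.31) and Cyp2c55 (-3.21 ± 0.65), enzymes of drug and toxin metabolism, also fell. H2-Q10, an MHC class I related gene, rose from 3.97 ± 1.66 to 66.5 ± 53.4 CPM (4.05 ± 0.65, adjusted p = 0.00374), and F10, which encodes coagulation factor X, by 2.03 ± 0.30. H2-Q10 lay between 76.05 and 131.7 CPM in HFD WT 1, 2, 3 and 7, where Hoxc6 was 1.056 to 1.782 CPM. It lay between 9.892 and 17.98 CPM in HFD WT 4, 5 and 6, where Hoxc6 was 0. All 7 lay above the highest ND WT library (7.25 CPM), but the size of the rise cannot be told apart from a difference in position. Of 17 carbohydrate handling genes 4 rose, or 9 adjusted over the list alone (adjusted p = 8.65e-07; adjusted p = 0.843 with an estimated correlation), among them Fbp1 (1.07 ± 0.19), Tkfc (0.86 ± 0.17) and Khk (0.73 ± 0.17). Mucl3, a mucin-like gene, fell from 310 ± 522 CPM on ND to 0.261 ± 0.501 CPM on HFD, and Psca, a surface antigen of stomach epithelium, from 79.5 ± 112 to 0.168 ± 0.121 CPM. Syt8 (-6.07 ± 1.21) and Anxa10 (-5.98 ± 1.53), an annexin of gastric epithelium, also fell, and both reversed sign without the 4 duodenum libraries with high Gkn1. Gkn1 lay over 100 CPM in 3 of the 6 ND WT libraries and in 0 of the 7 HFD WT libraries. In all 306 genes passed, 129 higher and 177 lower. Without the 4 high-Gkn1 libraries the count was 67, of which 29 were among the 306, with Cyp1a1 at -7.63 (adjusted p = 5.94e-07). Of 24 genes under the naming rule 6 then kept their call, namely F10, Cyp1a1, Cyp2c29, Gstm1, Cyp2c66 and Cyp2c55, while 16 lost it. With 3 ND WT libraries left, H2-Q10 was at 3.80 ± 0.96 (adjusted p = 0.0780), close to its value with all libraries, and Fbp1, Tkfc and Khk were at 0.87 ± 0.24, 0.60 ± 0.19 and 0.39 ± 0.15. Mucl3 and Psca were at -1.90 ± 1.58 and -0.52 ± 1.85. Without ND WT 2 alone Mucl3, Psca, Syt8, Anxa10, Tkfc and Khk lost their call (adjusted p from 0.0540 to 0.160). Mucl3 also lost it without HFD WT 2, 3, 4 or 7 (adjusted p up to 0.0556), Khk without these or ND WT 6 (up to 0.0716), and Anxa10 without these, ND WT 6, HFD WT 1 or HFD WT 6 (up to 0.0926). The count was 38 without ND WT 2, 140 without ND WT 6, 93, 100, 103 and 116 without HFD WT 2, 3, 4 and 7, and 927, 930 and 1002 without ND WT 3, ND WT 5 and HFD WT 5.

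In the duodenum of HET mice (n = 6 each) 6 of 25 xenobiotic genes were lower on HFD, or 16 adjusted over the list alone (adjusted p = 8.58e-27; adjusted p = 0.0318 with an estimated correlation). Cyp1a1 fell from 285 ± 166 (SD) to 0.555 ± 0.351 CPM (adjusted p = 2.19e-08). On the log2 scale, Cyp2c29 fell by 5.08 ± 0.78, and Ces2b, a carboxylesterase, fell by 3.48 ± 0.66. Gstm1 (-1.97 ± 0.27), Cyp2c66 (-2.30 ± 0.33) and Nqo1 (-1.02 ± 0.19), a quinone reductase, fell as well. H2-Q10 (3.80 ± 0.65) and Acot1 (2.54 ± 0.43), which hydrolyses fatty acyl-CoA, rose. As in WT, H2-Q10 was higher in the libraries with more Hoxc6. It lay between 78.68 and 98.88 CPM in HFD HET 3, 5 and 6 and between 10.51 and 20.39 CPM in HFD HET 1, 2 and 4, against at most 4.856 CPM on ND. T cell and intraepithelial lymphocyte markers were lower in 1 of 24 cases, Il2rb (-1.17 ± 0.24), or 13 adjusted over the list alone (adjusted p = 1.11e-16; adjusted p = 0.295 with an estimated correlation). Ces2b lost its call without ND HET 5, HFD HET 2 or HFD HET 4 (adjusted p up to 0.0591). Il2rb lost it without ND HET 2, 3 or 5 or HFD HET 2, 3, 4, 5 or 6 (up to 0.122). In all 41 genes passed, 10 higher and 31 lower. The count was 69 without the libraries with high Gkn1. It moved to 64, 99 and 26 without ND HET 4, HFD HET 1 and HFD HET 2. Of the genes past the threshold in WT and HET, 8 higher and 17 lower ones were shared, where independent lists would share 0.0768 and 0.327. The diet by genotype interaction passed for 0 genes in the duodenum by edgeR (1494 at an unadjusted p under 0.05; 0 by limma-voom and 1 by DESeq2), so no difference between the genotypes was shown.

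In the jejunum of WT mice 13 of 26 PPAR-driven fatty acid oxidation genes rose on HFD (n = 7 HFD, 6 ND), or 20 adjusted over the list alone (camera adjusted p = 1.58e-18; adjusted p = 0.0999 with an estimated correlation). Slc25a20 (0.84 ± 0.13 SE on the log2 scale), Cpt1a (0.57 ± 0.10) and Ech1 (0.89 ± 0.17) were in front. Cyp1a1 fell from 57.8 ± 43.3 to 0.0745 ± 0.0678 CPM (SD; 8 counts over the 7 HFD libraries; log2 fold change -9.45 ± 0.62 SE, adjusted p = 4.76e-13). H2-Q10 rose from 3.36 ± 1.18 to 95.7 ± 29.2 CPM (4.81 ± 0.34, adjusted p = 3.24e-09), G0s2, an inhibitor of triglyceride lipase, by 2.86 ± 0.50, Scarb1, a lipoprotein receptor, by 2.63 ± 0.32, and Cyp4a10, a fatty acid hydroxylase and PPARα target, by 2.58 ± 0.56. Of 28 fat absorption genes 5 rose, or 11 higher and 2 lower adjusted over the list alone (adjusted p = 8.00e-05; adjusted p = 0.603 with an estimated correlation), and of 25 cholesterol synthesis genes 4 rose, or 7 adjusted over the list alone (adjusted p = 1.04e-05; adjusted p = 0.557 with an estimated correlation). Interferon-stimulated genes fell in 13 of 29 cases, or 23 adjusted over the list alone (adjusted p = 6.98e-19; adjusted p = 0.0999 with an estimated correlation), led by Ifit1 (-1.81 ± 0.27), Gbp7 (-1.23 ± 0.21) and Oas3 (-1.25 ± 0.22). MHC class II presentation genes fell in 4 of 11 cases, or 11 adjusted over the list alone (adjusted p = 1.10e-07; adjusted p = 0.359 with an estimated correlation), among them Ctss (-0.97 ± 0.18) and H2-Ab1 (-1.87 ± 0.44). T cell markers fell in 10 of 23 cases, or 14 adjusted over the list alone (adjusted p = 8.02e-13; adjusted p = 0.359 with an estimated correlation), with Gzma (-1.70 ± 0.28) and Cd3g (-1.46 ± 0.26) in front. Npl (-3.75 ± 0.94), which breaks down sialic acid, Cyp2c29 (-3.71 ± 0.49), the antimicrobial lectins Reg3b (-3.42 ± 0.61) and Reg3g (-3.34 ± 0.58), and the chemokine Cxcl10 (-2.64 ± 0.55) fell as well. Npl was at -1.94 (adjusted p = 0.192) without ND WT 4. It also lost its call without HFD WT 2, 3, 4 or 5 (adjusted p up to 0.0659). Without ND WT 5 alone Cxcl10 was at -1.51 and H2-Ab1 at -1.55 (adjusted p = 0.0216 and 0.0642). In all 579 genes passed, 299 higher and 280 lower. The count was 622 without the 5 jejunum libraries of doubtful position, of which 442 were shared. It was 292, 305 and 369 without ND WT 5, HFD WT 2 and HFD WT 4.

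In the jejunum of HET mice 14 of 26 fatty acid oxidation genes were higher on HFD (n = 5) than on ND (n = 6), or 19 higher and 1 lower adjusted over the list alone (adjusted p = 1.10e-17; adjusted p = 0.223 with an estimated correlation). Cpt1a (0.92 ± 0.11 SE on the log2 scale), Acaa1b (1.52 ± 0.20) and Acadl (1.40 ± 0.20) led them. Cyp1a1 stood at 0.0823 ± 0.0737 CPM on HFD and 104 ± 70.1 CPM on ND (log2 fold change -10.16 ± 0.73 SE, adjusted p = 5.20e-12). H2-Q10 (4.60 ± 0.34), Trim50 (4.43 ± 0.67), a gastric ubiquitin ligase, and Cyp4a10 (3.96 ± 0.62) rose most. Fat absorption genes rose in 7 of 28 cases, or 12 higher and 3 lower adjusted over the list alone (adjusted p = 4.54e-05; adjusted p = 0.679 with an estimated correlation), including Plin2 (1.08 ± 0.13), a lipid droplet coat protein, Scarb1 (2.68 ± 0.34) and Mttp (1.06 ± 0.17), which loads chylomicrons. Ltc4s, the leukotriene C4 synthase of tuft cells, rose by 2.59 ± 0.24. Paneth cell markers fell in 1 of 14 cases, or 12 adjusted over the list alone (adjusted p = 3.64e-08; adjusted p = 0.679 with an estimated correlation). In all 818 genes passed, 567 higher and 251 lower. The count was 1545 without the doubted jejunum libraries, of which 721 were shared. It was 341 and 488 without HFD HET 4 and ND HET 4. WT and HET shared 199 higher genes (10.2 for independent lists) and 55 lower genes (4.21), and 290 of the 299 genes higher in WT had the same sign in HET. The interaction passed for 0 genes by edgeR (1092 at an unadjusted p under 0.05; 0 by limma-voom, 3 by DESeq2).

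**Figure D2:**
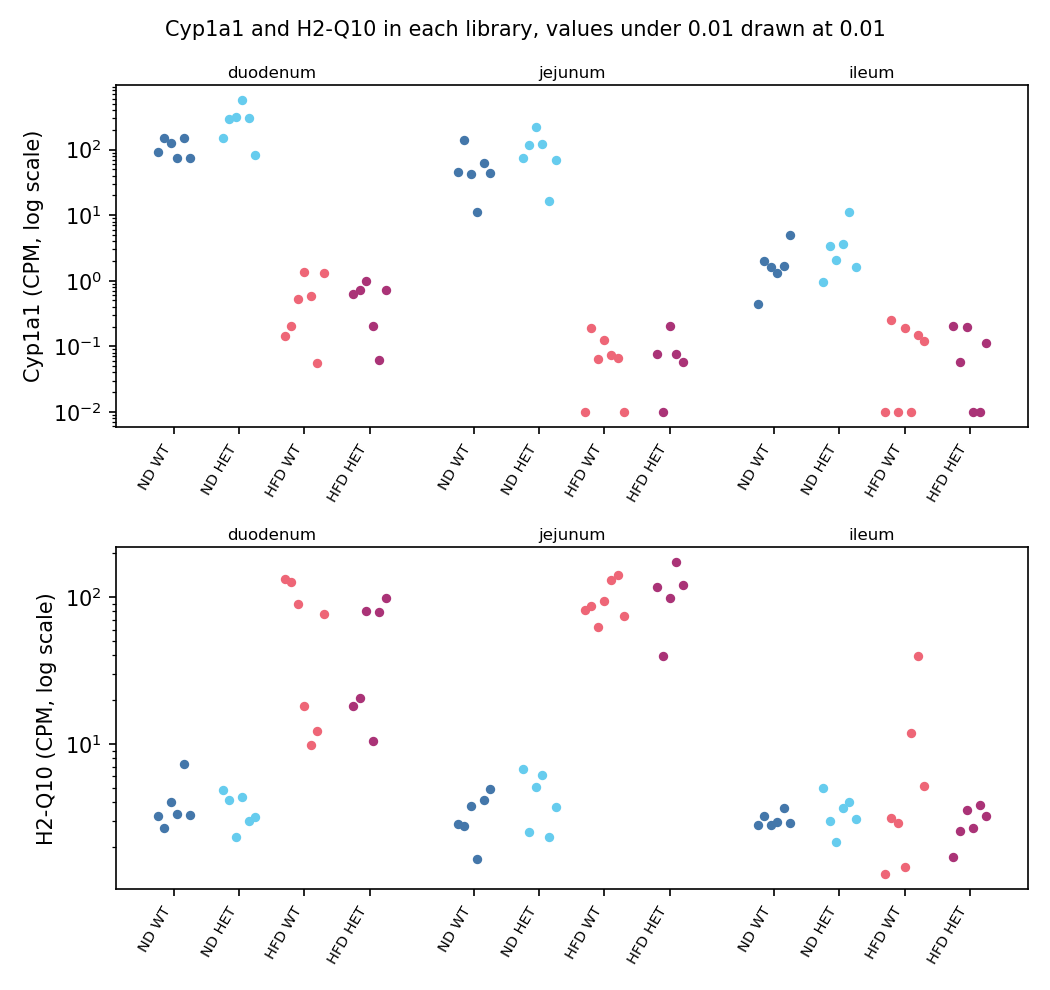
Cyp1a1 and H2-Q10 level of each library in CPM on log axes, scaled over all 74 libraries, with 1 point per library in each of the 12 groups and values under 0.01 drawn at 0.01. Cyp1a1 averages 111 CPM in the ND WT duodenum and 0.596 CPM on HFD, and H2-Q10 averages 3.36 CPM in the ND WT jejunum and 95.7 CPM on HFD.

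In the ileum of WT mice 24 of 26 fatty acid oxidation genes rose on HFD (n = 7 HFD, 6 ND), or 25 adjusted over the list alone (camera adjusted p = 5.82e-18; adjusted p = 0.163 with an estimated correlation). HFD WT libraries 2, 3, 5 and 6 are of doubtful position, and without them 416 genes passed in place of 3961. The values in this paragraph use all 7 HFD WT libraries unless stated. Of 27 fat absorption genes 21 rose, or 24 adjusted over the list alone (adjusted p = 1.14e-13; adjusted p = 0.244 with an estimated correlation). Cyp4a10 rose by 8.08 ± 1.00 on the log2 scale, Fabp1 by 7.51 ± 0.99 (from 15.9 ± 9.32 to 2814 ± 2432 CPM, SD) and Cym, an acid protease, by 6.96 ± 0.86. Fabp1 lay between 2946 and 6891 CPM in HFD WT 2, 3, 5 and 6. It stood at 1339, 296.2 and 157.8 CPM in HFD WT 1, 4 and 7. Carbohydrate handling genes rose in 16 of 17 cases, also adjusted over the list alone (adjusted p = 3.97e-14; adjusted p = 0.163 with an estimated correlation), led by Pck1 (3.80 ± 0.53), the gluconeogenic carboxykinase, and Slc37a4 (1.44 ± 0.21), the glucose-6-phosphate transporter. All 29 oxidative phosphorylation genes rose, as they did adjusted over the list alone (median 0.50; adjusted p = 2.21e-20; adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis genes fell in 21 of 25 cases, or 22 adjusted over the list alone (adjusted p = 1.43e-18; adjusted p = 0.163 with an estimated correlation), with Mvd (-1.65 ± 0.20), Hmgcs1 (-1.63 ± 0.19) and Fdft1 (-1.74 ± 0.22) in front. Microbe-responsive genes fell in 8 of 15 cases and rose in 1, or 9 and 1 adjusted over the list alone (adjusted p = 0.000354; adjusted p = 0.255 with an estimated correlation), led by Fut2 (-2.57 ± 0.44), a fucosyltransferase. Saa1 (-6.12 ± 1.17), an acute phase protein, Cyp3a44 (-5.32 ± 0.72) and Tat (-5.23 ± 1.10), the tyrosine aminotransferase, fell most. Cyp1a1 stood at 0.101 ± 0.103 CPM on HFD and 2.00 ± 1.54 CPM on ND (-4.16 ± 0.72), and Fa2h, a fatty acid hydroxylase, fell by 3.98 ± 0.82 (-2.465 without ND WT 6).

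In the same comparison proximal identity genes rose in 8 of 14 cases and fell in 1, or 10 and 1 adjusted over the list alone (adjusted p = 1.24e-05; adjusted p = 0.163 with an estimated correlation), including Cck (1.71 ± 0.27), Onecut2 (3.44 ± 0.62) and Apoa4 (6.57 ± 1.22). Hoxb9, a homeobox gene of the distal gut, fell by 3.56 ± 0.84. In HFD WT ileum libraries 2, 3, 5 and 6 Hoxb9 lay between 0.148 and 0.934 CPM and Fabp6 between 4.18 and 63.4 CPM, against 1.96 to 67.2 and 2393 to 6254 CPM in the other 21 ileum libraries. Gata4, a transcription factor of the duodenum and jejunum, lay between 72.0 and 110 CPM in the same 4 libraries and between 0.204 and 43.8 CPM in the others. In all 3961 genes passed, 2223 higher and 1738 lower. Without these 4 libraries, which leaves 3 HFD WT libraries, 416 genes passed, 385 of them shared. Of the 38 genes under the naming rule that could then be tested, 21 kept their call, among them Hmgcs1, Fdft1, Cyp4a10, Fabp1 and Cyp1a1 (-4.22, adjusted p = 0.0389). With the covariate for position 25 genes passed, and 35 of 40 genes under the naming rule lost their call. With covariates for muscle and lymphoid tissue 1894 passed, and all 40 kept it.

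**Figure D3:**
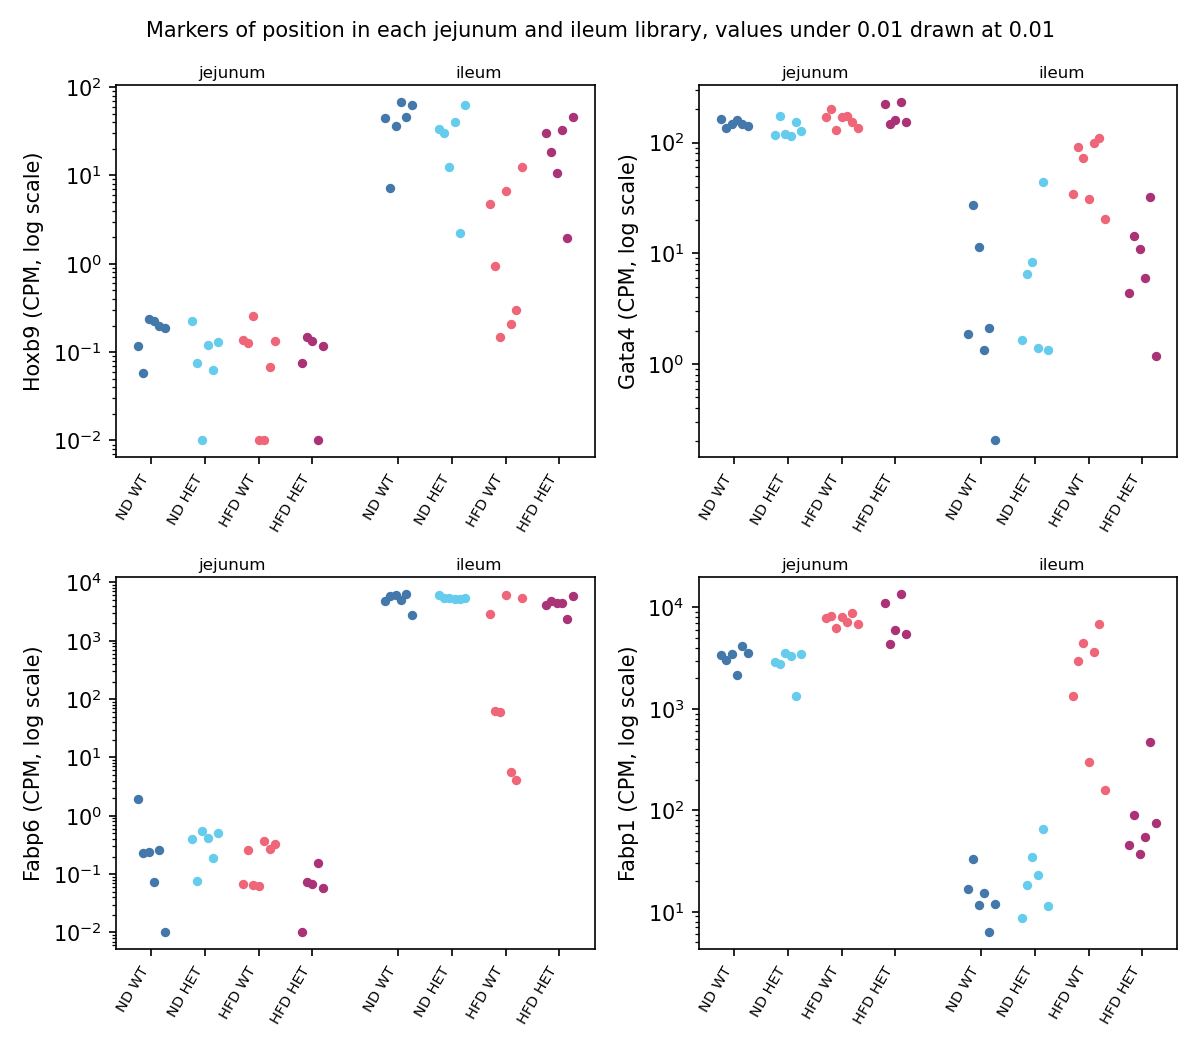
Hoxb9, Gata4, Fabp6 and Fabp1 level of each jejunum and ileum library in CPM on log axes, scaled over all 74 libraries, with 1 point per library and values under 0.01 drawn at 0.01. Of the 7 HFD WT ileum libraries 4 lie between 4.18 and 63.4 CPM of Fabp6, while the other 21 ileum libraries lie between 2393 and 6254 CPM.

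In the ileum of HET mice (n = 6 each) on HFD Cyp1a1 fell by 5.18 ± 0.70 on the log2 scale, Gbp2b, an interferon-induced GTPase, by 2.53 ± 0.37, Il1r2, a decoy receptor for interleukin 1, by 1.34 ± 0.24, and Ahrr, the repressor induced by the aryl hydrocarbon receptor, by 1.31 ± 0.24 (adjusted p from 0.000850 to 0.0259). Mmp12, a macrophage elastase, rose by 1.88 ± 0.35. Cholesterol synthesis genes fell in 1 of 25 cases, Mvd (-1.08 ± 0.20), or 22 adjusted over the list alone (camera adjusted p = 7.34e-32; adjusted p = 0.0782 with an estimated correlation). T cell markers were lower in 0 of 25 cases over all genes and in 10 adjusted over the list alone (adjusted p = 1.26e-17; adjusted p = 0.301 with an estimated correlation). The calls of Il1r2, Ahrr, Mvd and Mmp12 were lost without ND HET 2, 3, 4 or 6 or HFD HET 4 or 5. The first 3 were also lost without ND HET 1 or HFD HET 2, Il1r2 and Mmp12 without HFD HET 3, and Mvd and Mmp12 without HFD HET 1 (adjusted p in all of these from 0.0665 to 0.120). In all 11 genes passed, 2 higher and 9 lower. The count was 12 without the 4 doubted ileum libraries. All of these are HFD WT, so that fit keeps every HET library and does not test position in this comparison. The count moved to 98 without HFD HET 6 and 46 without ND HET 5, and fell to between 2 and 7 without each of 9 other libraries. Of the genes past the threshold in WT and HET ileum, 0 higher and 8 lower ones were shared, where independent lists would share 0.260 and 0.916. Of the 2223 genes higher in WT 1563 had the same sign in HET, and of the 1738 lower ones 1263 had.

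On HFD, 23 of 27 fat absorption genes were lower in HET than in WT ileum (n = 6 HET, 7 WT), or 24 adjusted over the list alone (camera adjusted p = 5.71e-12; adjusted p = 0.318 with an estimated correlation). Without the 4 WT libraries with low Hoxb9, however, 0 genes of the whole comparison passed by edgeR (3094 at an unadjusted p under 0.05). The fat absorption list was led by Soat2 (-1.40 ± 0.24 SE on the log2 scale), which esterifies cholesterol, Dgat2 (-2.26 ± 0.40), which makes triglyceride, and Acsl5 (-1.87 ± 0.35). The log2 fold change was -7.36 ± 1.06 for Sult6b2, a sulfotransferase, -6.39 ± 0.81 for Cym and -6.35 ± 1.16 for Cyp2b10, a xenobiotic cytochrome. Krt84 (2.76 ± 0.55), a keratin, Hoxb9 (2.64 ± 0.82) and Cfd (2.50 ± 0.77), the adipocyte complement factor, were higher, though Cfd was at 1.51 (adjusted p = 0.112) without HFD HET 5. Carbohydrate handling genes were lower in 15 of 17 cases, or 16 adjusted over the list alone (adjusted p = 1.84e-13; adjusted p = 0.318 with an estimated correlation), with Tkfc (-1.21 ± 0.17), Slc37a4 (-1.46 ± 0.21) and Treh (-4.31 ± 0.64), the trehalase of the brush border, in front. All 29 oxidative phosphorylation genes were lower, also adjusted over the list alone (median -0.43; adjusted p = 7.75e-15; adjusted p = 0.318 with an estimated correlation). Proliferation genes were higher in 22 of 25 cases and lower in 1, or 23 and 1 adjusted over the list alone (adjusted p = 8.52e-07; adjusted p = 0.549 with an estimated correlation), led by Plk1 (0.77 ± 0.16) and Cdc20 (0.86 ± 0.22). Goblet cell markers were higher in 7 of 15 cases, or 9 adjusted over the list alone (adjusted p = 0.00444; adjusted p = 0.582 with an estimated correlation), among them Agr2 (0.84 ± 0.21) and Spdef (0.61 ± 0.17). Of 27 RIPK1 and TNF receptor signalling genes 7 were lower, or 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.582 with an estimated correlation), among them Ticam1 (-0.67 ± 0.15), Tnfaip3 (-0.74 ± 0.18) and Tbk1 (-0.82 ± 0.21). The list of genes next to Ripk1 on its chromosome went both ways, with 6 of 35 higher and 9 lower, or 6 and 10 adjusted over the list alone (adjusted p = 0.812).

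Between the same groups proximal identity genes were lower in HET in 8 of 14 cases and higher in 1, or 9 and 1 adjusted over the list alone (adjusted p = 0.000361; adjusted p = 0.318 with an estimated correlation), and smooth muscle markers were higher in 12 of 20 cases, or 16 adjusted over the list alone (adjusted p = 3.37e-05; adjusted p = 0.549 with an estimated correlation). Fabp6 averaged 2057 ± 2693 CPM (SD) in WT and 4332 ± 1106 CPM in HET, and Fabp1 2814 ± 2432 and 128 ± 167 CPM. In all 5015 genes passed, 2293 higher and 2722 lower. The count was 0 without the 4 low-Hoxb9 libraries, 2 with the covariate for position and 0 by edgeR with covariates for muscle and lymphoid tissue (2397 at an unadjusted p under 0.05). It was 3303 and 3321 without HFD HET 4 and HFD HET 3.

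The interaction of diet and genotype in the ileum passed for 447 genes, 133 higher and 314 lower. The interaction was negative for Cyp2b10 (-8.04 ± 1.51 on the log2 scale), Bbox1 (-6.15 ± 1.45), which makes carnitine, and Slc23a1 (-5.80 ± 0.99), a vitamin C transporter. With diet these genes rose in WT, by 6.01 ± 1.14, 6.37 ± 0.99 and 6.33 ± 0.80, while in HET the log2 fold changes of -2.03 ± 1.03, 0.22 ± 1.04 and 0.53 ± 0.66 missed the threshold (adjusted p = 0.543, 0.973 and 0.853). Slc23a1 averaged 154 ± 107 CPM (SD, n = 7) in HFD WT, 1.91 ± 2.21 in ND WT, 7.78 ± 4.87 in HFD HET and 5.44 ± 5.29 CPM in ND HET (n = 6 each). Carbohydrate handling genes had a negative interaction in 11 of 17 cases, or 16 adjusted over the list alone (camera adjusted p = 1.72e-16; adjusted p = 0.183 with an estimated correlation), and so had 7 of 29 oxidative phosphorylation genes, or 28 adjusted over the list alone (adjusted p = 8.58e-18; adjusted p = 0.264 with an estimated correlation). The mast cell proteases Mcpt2 (2.62 ± 0.60) and Mcpt1 (2.51 ± 0.64) had a positive interaction and Il33, an alarmin, a negative one (-2.50 ± 0.49). The α-defensins Defa21 and Defa2, whose near-identical copies share reads, averaged 266 ± 296 and 66.5 ± 73.8 CPM in HFD HET and 0.0298 ± 0.0329 and 0.0181 ± 0.0280 CPM in ND HET. The count was 0 by edgeR without the 4 low-Hoxb9 libraries (1235 at an unadjusted p under 0.05) and 0 with covariates for muscle and lymphoid tissue, and 1 with the covariate for position. It lay between 13 (without ND WT 1 or HFD HET 1) and 810 (without HFD WT 7) when single libraries were left out. Cyp2b10, Bbox1, Mcpt2, Mcpt1, Il33, Defa21 and Defa2 lost their call without any 1 of ND WT 1, ND HET 5 and HFD HET 1 (adjusted p up to 0.0867). They lost it in 5, 14, 9, 18, 5, 16 and 19 of the 25 fits with 1 library left out.

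The other 5 comparisons of HET with WT passed for 0 genes each by edgeR. On HFD, Ubald2 had the smallest p in the duodenum (log2 fold change -0.65 ± 0.12, adjusted p = 0.301; 795 genes at an unadjusted p under 0.05; limma-voom 0 and DESeq2 5), and Tert, the telomerase reverse transcriptase, in the jejunum (-0.79 ± 0.15, adjusted p = 0.145; 2400 genes; limma-voom 0 and DESeq2 50). On ND it was Plb1, a phospholipase, in the duodenum (-2.33 ± 0.45, adjusted p = 0.303; 2138 genes; limma-voom 0 and DESeq2 18). In the ND jejunum the predicted gene Gm3054 came first (1.83 ± 0.43, adjusted p = 1.00; 435 genes; limma-voom 0 and DESeq2 1), and in the ND ileum the predicted gene Gm5420 (-1.96 ± 0.37, adjusted p = 0.263; 1335 genes; limma-voom 0 and DESeq2 16). Simulated changes of 2-fold were recovered in 62.7% of cases in the HFD duodenum and 68.7% in the HFD jejunum. The simulations drew each gene independently, without differences between libraries that many genes share, so recovery in the real libraries can differ.

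The effect of genotype on HFD differed between the segments for 1478 genes. Cym had the smallest p (adjusted p = 1.78e-08), with log2 fold changes of 0.35 ± 0.38 in the duodenum, 0.38 ± 0.24 in the jejunum and -6.39 ± 0.81 in the ileum. Treh came next (adjusted p = 6.52e-08), at 0.03 ± 0.29, 0.23 ± 0.15 and -4.31 ± 0.64. The count was 0 by edgeR without the libraries of doubtful position (2406 at an unadjusted p under 0.05) and 0 with the covariate for position, and 3206 with the mouse that the labels imply as a block. Without single libraries it lay between 686 (ileum HFD HET 3) and 2871 (jejunum HFD HET 5).

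The effect of diet in WT differed between the segments for 1897 genes. Cyp2c66 fell in the duodenum (-1.97 ± 0.31) and jejunum (-2.14 ± 0.27) and rose in the ileum (4.44 ± 0.75; adjusted p of the difference = 4.66e-10). Fabp1 rose by 1.20 ± 0.27, 1.19 ± 0.23 and 7.51 ± 0.99 in the same order (adjusted p = 3.96e-09). Without the libraries of doubtful position 1081 genes passed, 626 of them shared, and without duodenum ND WT 2 the count was 1259.

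The fold changes of genotype on HFD ran opposite to those of diet in WT in the ileum. Over 17073 genes, which are not independent replicates, the correlation was -0.794 and the covariance -0.224 with the same HFD WT libraries in both. Simulations with no effect of diet or genotype gave -0.450 and -0.0317 on average, and 0 of 500 gave a covariance as low. They dealt the residuals of the 3 groups at random, so they do not keep a larger spread in HFD WT. The SD of ileal Fabp6 was 2693 CPM in HFD WT and 1106 CPM in HFD HET. The 0 of 500 can therefore overstate the opposition. With the HFD WT libraries divided into sets of 3 and 4 for the 2 differences, the correlation averaged -0.606 over 35 divisions (range -0.683 to -0.373). The jejunum gave -0.463 unsplit, -0.446 in simulations and -0.251 split, with 59 of 500 simulated covariances as low, and the duodenum -0.384, -0.449 and -0.0837, with 202 of 500. The 4 low-Hoxb9 libraries are among the HFD WT ileum libraries of both differences.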

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

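The tests of position, of tissue share and of a diet effect in the ileum, both tests of the lower duodenal genes, the test of Cyp1a1 with the covariate for position, the tests of Cyp1a1 and Ahrr within a genotype and the splits that part every mouse were chosen only after the results were seen, as were the covariate itself and the criteria for libraries of doubtful position. The ileal test of a diet effect replaced one on 5007 genes called in the same comparison (median 0.55 with all libraries, 0.35 without the 4 libraries), which was void because its genes were picked for the pattern. The duodenal test of a diet effect replaced one in the WT libraries themselves (median -1.86, and -2.27 without the high-Gkn1 libraries).

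The first pattern is the set of 5015 genes that differed between HET and WT ileum on HFD, of which 0 passed by edgeR without HFD WT libraries 2, 3, 5 and 6 (3094 at an unadjusted p under 0.05), and 0 with covariates for muscle and lymphoid tissue (2397), where all 56 genes under the naming rule lost their call. A different share of muscle wall and lymphoid tissue would dilute Fabp1 and Fabp6 alike. Their log2 ratio differed by -8.70 between HET and WT (-5.68 against 3.02; exact permutation p = 0.0140, n = 6 and 7), which dilution alone does not give for these 2 genes. Both genes were chosen after their levels in the 4 libraries were seen, so the ratio does not test the cause for the other genes. With the loss under these covariates, a different tissue share stays open for the set. Pieces taken at different places along the ileum stay open and cannot be told apart from a change of ileal identity: Hoxc6, Hoxc8 and Hoxc9, taken relative to smooth muscle genes of the same library, were higher in HET by 0.80 (-3.49 against -4.30), but these genes were chosen after their low levels in the 4 libraries were seen, so the difference does not test it. A diet effect on ileal identity that HET mice lack stays open: over 1549 genes that separate the 4 libraries from ND WT, the other 3 HFD WT libraries differed from HFD HET by 0.32 in that direction (exact permutation p = 0.0238 over 84 arrangements), against 1.41 for the 4 libraries, and with 3 libraries left it cannot be told apart from a milder difference in position. A biological difference between the genotypes is not excluded by these tests.

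The second pattern is the set of 177 genes lower on HFD in WT duodenum. For the 6 xenobiotic genes among them the median log2 fold change was -2.24 in HET duodenum without the high-Gkn1 library ND HET 6, with 6 of 6 lower. WT does not share these libraries, so the values go with a diet effect on duodenal tissue for these 6 genes. Stomach tissue in ND WT pieces cannot be told apart from a diet effect for the 171 other genes: their median was -0.81 with all libraries and -0.55 without the 4 high-Gkn1 libraries (68.7% kept). These genes were picked as lower in this same comparison, whose remaining libraries give the second median, so the share kept does not test the cause. In HET duodenum without ND HET 6 their median was -0.14.

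The third pattern is the lower Cyp1a1 on HFD in all 6 diet comparisons. Pieces taken at different places along the intestine are argued against as the whole cause, since with the covariate for position Cyp1a1 stayed past the threshold in 6 of 6 comparisons (adjusted p up to 0.0367). Less activity of the aryl hydrocarbon receptor on HFD stays open: over the 12 ND mice Cyp1a1 and Ahrr deviated from their group means with r = 0.412 (permutation p = 0.181; Spearman's rho 0.462, permutation p = 0.134), and with r = 0.417 without the 2 mice farthest from the median. Within the genotypes r was 0.0999 in the 6 WT mice (exact permutation p = 0.860; rho -0.029, exact permutation p = 1.00) and 0.701 in the 6 HET mice (exact permutation p = 0.124; rho 0.771, exact permutation p = 0.103), and over these 3 relations the smallest adjusted p was 0.271. A relation among ND mice does not test the effect of diet. Ahrr itself averaged lower on HFD than on ND in all 3 segments of both genotypes, at low levels. In WT it went from 1.525 to 0.955 CPM in the duodenum, 1.49 to 0.429 in the jejunum and 2.57 to 0.863 in the ileum. In HET it went from 1.49 to 0.802, 1.39 to 0.466 and 3.37 to 1.35 CPM in the same order. A diet component that activates the receptor was not measured here.

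Genes were also counted in 100 splits of the same libraries into groups of the real sizes, the real one included. For 10 of the 12 counts above 0, at most 3 of the 100 splits gave as many genes, without adjustment over the 12 counts. As many genes as in the real grouping were called in 1 split, the real one, for WT jejunum with diet (579; highest other 4), WT ileum with diet (3961; 3859), HET duodenum with diet (41; 1), ileum against duodenum (7012; 3733) and the differences between segments in genotype effect (1478; 417) and diet effect (1897; 643). The number was 2 for HET against WT ileum on HFD (5015; 5098), the ileal interaction (447; 911) and jejunum against duodenum (2546; 2746), and 3 for HET ileum with diet (11; 410). In each of these another split gave more genes than the real grouping, so these splits do not exclude chance there. Nor can chance be excluded for WT duodenum with diet (306; 1405, with 7 splits as large) or HET jejunum with diet (818; 3308, with 6 splits as large). For the 7 counts of 0 all 100 splits give as many by construction, so that chance was not tested there, with highest others of 147, 672, 1455, 7, 1648, 730 and 350 for HET against WT in HFD duodenum and jejunum, in ND duodenum, jejunum and ileum, and for the interactions in duodenum and jejunum. The splits with several times the real number, as in WT duodenum, HET jejunum and HET ileum, point to a structure of the samples other than the groups, whose nature was not tested. For the differences between segments all libraries of a mouse were moved together, whereas the splits of ileum or jejunum against duodenum moved single libraries. Over the 32 splits that part the 2 libraries of each of the 6 mice, the real one alone gave as many genes for ileum against duodenum (highest other 4091) and for jejunum against duodenum (highest other 2109).

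Of 125 sets of values within groups, 25 held 1 library whose gap to its nearest neighbour was large for the range of its group. Chance gives such a gap in about 1 in 20 groups if values are normal and independent. CPM values need not be normal, the sets include Hox genes and their mean, and markers of position were chosen after their values were seen. The 25 of 125 therefore cannot be set against that rate. Total counts stood apart in duodenum HFD HET 3 (16313874) and jejunum ND HET 2 (17127885). In the jejunum the mean log2 CPM of the 11 Hox genes stood apart in ND WT 4 (1.15) and HFD WT 7 (0.882), Hoxc6 in ND WT 4, ND HET 5 and HFD WT 7 (13.3, 16.3 and 7.99 CPM), and Hoxc8 in ND WT 4, ND HET 5, HFD WT 7 and HFD HET 2 (5.28, 6.89, 2.80 and 5.60 CPM). Jejunum ND HET 5 was also lowest in Fabp1 (1348 CPM), and jejunum ND WT 1 highest in Fabp6 (1.92 CPM). In the ileum Hoxc9 stood apart in ND WT 6 (8.35 CPM), Gata4 in ND HET 5 (43.8 CPM), Fabp1 in HFD HET 5 (466.8 CPM) and Fabp6 in ND HET 1 (5967 CPM). Cyp1a1 was apart in ileum ND WT 6 and ND HET 5 (4.94 and 11.1 CPM), and H2-Q10 in duodenum ND WT 5 (7.25 CPM) and ileum HFD WT 6 (39.4 CPM). In the duodenum Gkn1 stood apart in ND WT 2, ND HET 6 and HFD HET 1 (2937, 192.9 and 8.08 CPM) and Gata4 in ND WT 1 (224.8 CPM).

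The effect of diet differed between the genotypes in the ileum by the test of the interaction itself for 447 genes. The count by edgeR was 0 without the libraries of doubtful position (1235 at an unadjusted p under 0.05) and 0 with covariates for muscle and lymphoid tissue, where all 16 genes named next lost their call, and 1 with the covariate for position, where 15 of the 16 lost it. The log2 interaction was 4.58 for Cfd and 3.68 for Car3, both adipocyte genes, 2.62 for Mcpt2 and 2.51 for Mcpt1. It was -8.04 for Cyp2b10, -6.15 for Bbox1, -5.80 for Slc23a1, -5.24 for Fabp1, -4.04 for Treh, -3.27 for Pck1, -3.16 for Gstm6, -2.50 for Il33, -1.63 for Slc37a4 and -1.54 for Soat2. The fitted 14.27 for Defa21 and 12.38 for Defa2 depend on the prior count, since the ND HET libraries held 3 and 2 counts of them. Without any 1 of ileum ND WT 1, ND HET 5 and HFD HET 1, all of these genes but Slc23a1 and Slc37a4 lost their call (adjusted p up to 0.0867).

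Effects differed between the 3 segments by a test of the difference for 1478 genes in genotype on HFD and 1897 genes in diet in WT. Without the libraries of doubtful position the counts by edgeR were 0 (2406 at an unadjusted p under 0.05) and 1081, and with the covariate for position 0 and 654. For genotype the smallest adjusted p were those of Cym (1.78e-08), Treh (6.52e-08), Cyp2b10 and Adora2b (4.48e-06 each), Slc2a2 (5.66e-06) and Dhrs1 (7.07e-06). For diet they were those of Cyp2c66 (4.66e-10), Fabp1 (3.96e-09), Cym (5.81e-08), Cyp2b10 (9.19e-08) and Ptgr1 (1.11e-07).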

How the results depend on the processing

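The covariate for position and the fits without 13 libraries of doubtful position were chosen only after the results were seen. Leaving out single libraries was not planned for the interactions or for the comparisons between segments. All other alternatives were planned before the data were examined.

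Of the 306 values of named genes, all 306 kept their direction and side of the threshold with RLE and upper quartile scaling, 303 with the earlier edgeR pipeline, 279 with limma-voom and 279 without a filter. With covariates for muscle and lymphoid tissue 88 were no longer past the threshold, with the covariate for position 118, and without the libraries of doubtful position 131 of 299. Syt8 (0.36) and Anxa10 (2.02) reversed there for HFD against ND in WT duodenum. The replicate number as a block left 33 short of the threshold. Where a count fell with fewer libraries, fewer samples entered the fit, and for other changes the cause was not tested.

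For counts of passing genes, D, J and I stand for duodenum, jejunum and ileum, and WT or HET for the diet effect in that genotype. Also requiring an absolute log2 fold change of at least 1 left 107 in WT D, 218 in WT J, 240 in HET J, 822 in WT I, 682 for HET against WT in HFD I, 262 for the I interaction, 980 for J against D and 2737 for I against D. With limma-voom the counts were 203 in WT D and 278 for the I interaction. With DESeq2 they were 953 in WT D, 136 in HET D, 911 in WT J, 89 in HET I and 904 for the I interaction. Where edgeR called 0, DESeq2 called 5 for HET against WT in HFD D, 50 in HFD J, 18 in ND D, 1 in ND J and 16 in ND I, and 1 and 3 for the D and J interactions. With only the 2 groups compared they were 1 for HET against WT in HFD D and 1 in ND D, 57 in WT D, 957 in WT J, 156 in HET J and 4 in HET I. Without a filter they were 353 in WT J, 477 in HET J, 43 for the I interaction, and 670 and 1033 for differences between segments in genotype and diet effects.

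With covariates for muscle and lymphoid tissue the counts were 159 in WT D, 168 in HET D, 5 for HET against WT in HFD J, 0 in HFD I, 1894 in WT I, 5 in HET I, 0 for the I interaction and 591 for the difference between segments in genotype effect. With the covariate for position they were 1278 in WT J, 1232 in HET J, 25 in WT I, 2 for HET against WT in HFD I, 1 for the I interaction, and 0 and 654 for differences between segments in genotype and diet effects. Without the libraries of doubtful position they were 67 in WT D, 69 in HET D, 1545 in HET J, 416 in WT I, 0 for HET against WT in HFD I, 0 for the I interaction, 11 for J against D, and 0 and 1081 for differences between segments in genotype and diet effects. Ripk1 in HFD I stood at -0.32, -0.32 and -0.52 under these 3 alternatives, short of the threshold, and Ripk1 in HFD J at 0.000263 with the tissue covariates. Of 261 lists past the threshold 5 were so with an estimated correlation.

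Numbers shared across groups of a segment do not pair the libraries: of 105 same-numbered pairs 37 had r over 0.1 (mean -0.000436), and in 17 pairs the library correlated best with its own number. With the replicate block the counts were 50 in WT D, 242 in WT J, 429 in HET J, 5 in HET I, 1 for HET against WT in ND I, 884 for the I interaction and, with the mouse as block, 3206 for the difference between segments in genotype effect. The block moved no other count by over 1.5 times.

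Leaving out 1 library at a time gave 38 (without ND WT 2) to 1002 (HFD WT 5) in WT D, with 140, 927 and 930 without ND WT 6, 3 and 5 and 93, 100, 103 and 116 without HFD WT 2, 3, 4 and 7. HET D ranged from 26 (HFD HET 2) to 99 (HFD HET 1), with 64 without ND HET 4. WT J ranged from 292 (ND WT 5) to 599 (HFD WT 1), with 305 and 369 without HFD WT 2 and 4. HET J ranged from 341 (HFD HET 4) to 1185 (HFD HET 5), with 488 without ND HET 4. WT I ranged from 2799 to 4253. HET I ranged from 2 (ND HET 2, 3 and 6, HFD HET 4 and 5) to 98 (HFD HET 6), with 3, 4 and 46 without ND HET 1, 4 and 5 and 5 and 7 without HFD HET 2 and 3. HET against WT in HFD I ranged from 3303 (HFD HET 4) to 6008 (HFD HET 6), with 3321 without HFD HET 3. Counts for HET against WT reached 9 and 1 in HFD J (without HFD HET 5 and 1), 1 in ND D (ND HET 6) and 1 in ND I (ND HET 5), from 0. HFD D and ND J stayed at 0 by edgeR. The D and J interactions ranged from 0 to 1 (HFD HET 6 and HFD HET 5). The I interaction was 13 without ND WT 1 or HFD HET 1, 130, 147, 87 and 15 without ND WT 3, 4, 5 and 6, 89, 82 and 14 without ND HET 2, 3 and 5, 718, 198, 102, 741, 29, 58 and 810 without HFD WT 1 to 7, and 30, 15 and 292 without HFD HET 3, 4 and 6. J against D ranged from 932 (duodenum ND WT 2) to 3362, with 1657 without ND WT 6, and I against D from 6302 to 7210. The difference between segments in diet effect ranged from 1259 (duodenum ND WT 2) to 2396, and that in genotype effect from 686 (ileum HFD HET 3) to 2871 (jejunum HFD HET 5), with 858 without jejunum HFD HET 2, 875 and 725 without ileum HFD WT 5 and 6, and 769 and 729 without ileum HFD HET 1 and 4. Ripk1 ranged from -0.32 to -0.16 in HFD D, -0.22 to -0.17 in ND D, -0.099 to 0.033 in HFD J (without HFD WT 2 and HFD WT 1; 0.018 without HFD HET 5), -0.29 to -0.10 in ND J, -0.68 to -0.51 in HFD I (adjusted p from 0.00329 to 0.0296) and -0.62 to -0.41 in ND I. Of 4343 values of named genes 352 lost and 4 gained a call, and 58 genes lost it at least once.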

Other observations

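The average of Ripk1 over the segments of each mouse was computed only after the results per segment were seen, while the gene lists were planned before the data were examined.

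Taken per mouse over its segments, Ripk1 was lower in the 12 HET mice than in the 13 WT mice, with a difference of -0.29 on the log2 scale, or 82.0% of WT (permutation p = 0.00061, 100000 resamples). The difference was -0.28 on ND (exact permutation p = 0.0108) and -0.29 on HFD (exact permutation p = 0.0221). This average takes the same number in different segments as the same mouse, as the titles imply. Core clock genes, whose level follows the time of day, deviated together across segments in libraries of the same number, with a mean r of 0.730 over 73 pairs, 72 of them over 0.1.

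Where no single gene passed over all genes by edgeR, some lists were past the threshold between HET and WT with the correlation preset in camera, and 0 lists were with an estimated one. In the HFD jejunum (n = 5 HET, 7 WT; 2400 genes at an unadjusted p under 0.05), 12 of 29 interferon-stimulated genes were higher in HET adjusted over the list alone (median log2 fold change 0.46; camera adjusted p = 1.05e-08; adjusted p = 0.775 with an estimated correlation). Of 14 Paneth cell markers, antimicrobial genes of the crypt base, 11 were lower adjusted over the list alone (median -1.57; adjusted p = 6.50e-10; adjusted p = 0.775 with an estimated correlation). Of 18 enteric neuron and glia markers 10 were higher adjusted over the list alone (median 0.92; adjusted p = 9.30e-05; adjusted p = 0.775 with an estimated correlation). In the HFD duodenum (795 genes at an unadjusted p under 0.05) 7 of 10 B cell and follicle markers were lower adjusted over the list alone (median -1.46; adjusted p = 0.000360; adjusted p = 0.999 with an estimated correlation). In the ND duodenum (2138 genes) 17 of 23 pancreatic acinar genes were higher in HET adjusted over the list alone (median 3.64; adjusted p = 4.23e-07; adjusted p = 0.621 with an estimated correlation). There Gkn1 lay over 100 CPM in ND WT 2, 4 and 6 and in ND HET 6, so the pieces of the 2 groups were not alike. Without these 4 libraries 1292 genes stood at an unadjusted p under 0.05. In the ND jejunum (435 genes) 6 of 9 B cell and follicle markers were lower adjusted over the list alone (median -1.54; adjusted p = 0.000306; adjusted p = 0.802 with an estimated correlation).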
